A study of Mus musculus and Homo sapiens with 4 samples.

How the data were processed

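Total RNA from 4 established cell lines, the mouse osteosarcoma line LM8 and the human melanoma line A375M each infected with a control or a Merm1 hairpin retrovirus, was hybridised as biotinylated cRNA to Affymetrix 3' arrays, per the labels' protocols. The 4 groups held 1 array each, and groups were taken from the sample titles. The deposited values were log2 expression values per probe set, made by the authors with RMA, per the submitters' processing notes, which give no version. RMA subtracts background, equalises the distributions of the arrays and summarises the probes of a probe set. Sorted values of the arrays of 1 line differed by at most 0.064 in LM8 and 0.075 in A375M, so their distributions were nearly equal and a global shift of expression would not be seen. Whether all arrays of a platform were processed together, and with which software, is not given in the sources used here. The mouse and human arrays are different designs, and levels were not compared between them.

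On the human arrays 24837 of 54675 probe sets had identical values in both arrays, including 21.5% of those in the brightest 20%, and 67.3% of probe sets had a control value that recurred in another probe set, with the most frequent value shared by 838. On the mouse arrays 318 of 45101 were identical and 13.1% recurred. The step that produced the recurring values is not given in the sources used here. Values were compared for exact equality.

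Probe sets were named through the platform annotation supplied with the tables, with mouse list members also matched through synonyms in a RefSeq table of assembly GRCm38.p6, and old histone symbols through their current names. Of the non-control probe sets, 34945 of 45037 in mouse and 41091 of 54613 in human had 1 gene symbol, 932 and 1801 had several, and 9160 and 11721 had none. Probe sets with several symbols or none named no gene. A gene was represented by its probe set with 1 symbol and the highest mean of the array pair, and was kept when that level lay above the 50th percentile of non-control probe sets in at least 1 array. This kept 11646 of 18193 named genes in LM8 and 13244 of 19773 in A375M. No genome coordinates were used here. Some transcripts, p53 itself and mouse Bax among them, were not analysed here.

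Differences were taken as knock-down minus control on the log2 scale and counted at 2-fold, with 1.5-fold and 3-fold as alternatives. Within a line there was no test, p-value or standard error, since each group held 1 array. The labels name the line of each array, so the lines pair the arrays, and a limma fit of the mean of the 2 differences per gene, with the line as a block and Benjamini-Hochberg adjustment, was added after the values were seen. It treats a mouse and a human line as replicates. Before the data were examined, 22 gene lists, 8 marker lists, the thresholds, the alternatives and the rule for named genes were fixed. A list with at least 5 kept genes was described by its median difference and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins and drawn with replacement, and stood apart below 2.5 or above 97.5. Genes of 1 list are regulated together, so these percentiles describe these arrays and say nothing about other cultures. The named genes were the target gene, the 12 kept genes with the highest and the 12 with the lowest difference in each line whose kept probe sets all had the same sign, up to 4 members with the largest differences of each list that stood apart, genes at least 2-fold different in the same direction in both lines, and p53, PLAGL1, CDKN1A, MDM2 and BAX whatever their values. Predicted genes without a standard symbol were to be counted and not named, and there were 0 among the genes at least 2-fold different.

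The alternatives were no filter on low values, a filter at the 70th percentile, arrays centred on their medians, repeated quantile normalization, removal of a loess curve on mean level (span 0.4), the mean of a gene's probe sets, exclusion of probe sets whose names end in _x_at or _s_at, which mark probes shared between transcripts, 32 added to the linear value before the log2, and random lists not matched on level. The scripts were tested on simulated data in which 200 genes were shifted. Among 11646 LM8 genes 98 of 100 with a log2 shift of 1.5 and 5 of 100 with a shift of 0.7 passed the 2-fold threshold, and among 13244 A375M genes 100 of 100 and 2 of 100 did. In the limma fit over both lines 197 of 200 genes shifted alike by 1.5 in both, and 1 of the others among 8981 genes, had an adjusted p under 0.05. That shift was equal in both lines and larger than the differences of most genes. The recovery therefore does not hold for smaller or unequal differences. Of 100 random unshifted lists 7 in LM8 and 6 in A375M lay outside the limits.

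Control probe sets gave a check of each array pair. The 18 hybridisation spike-in probe sets had a median difference of -0.00045 in LM8 and 0.056 in A375M (0.011 and 0.025 after centring the arrays on their medians). The 24 poly-A spike-in probe sets had a median difference of 0.14 in LM8, with 23 higher, and 0.026 in A375M, with 14 higher (0.15 and -0.0041 after centring). The 3' minus 5' difference of Gapdh was -0.18 in both LM8 arrays, and 0.091 in the control and 0.10 in the knock-down array of A375M. For Actb it was 0.35 and 0.34 in LM8, and 0.91 and 1.00 in A375M. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.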

Results

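Expression was measured on 4 Affymetrix 3' arrays, 1 for each of 4 stably infected cell lines. LM8 is a mouse osteosarcoma line and A375M is a human melanoma line. Each line carried either a control retroviral vector or a vector expressing a short hairpin RNA against Merm1, also called Wbscr22 and now named Bud23 in mouse and BUD23 in human, which encodes a methyltransferase of 18S ribosomal RNA. The mouse array held 45101 probe sets and the human array 54675. The values were log2 RMA expression values, and every difference below is the log2 value in the knock-down array minus that in the control array of the same line. With 1 array per group no difference within a line has a replicate check or a p-value, and the number of arrays limits the precision. As a technical gauge, the SD between probe sets of 1 gene had a median of 0.12 in LM8 and 0.071 in A375M, which leaves out the spread between cultures and between independently derived lines. The arrays of 1 line correlated across probe sets, which are not independent replicates, with Pearson's r of 0.996 in LM8 and 0.998 in A375M. In A375M 45.4% of probe sets had identical values in both arrays, which raises that r and can narrow that SD.

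The first question was how far the hairpins lowered their target. In LM8 the Bud23 probe set read 10.61 in the control array and 8.48 in the knock-down array, a difference of -2.13, or 4.37-fold lower with 22.9% of the control level left. It was the fourth lowest difference among 45037 non-control probe sets. In A375M the BUD23 bright probe set read 10.70 in the control array and 8.38 in the knock-down array, a difference of -2.32, or 4.99-fold lower with 20.04% left, and the lowest among 54613 non-control probe sets. A second human probe set lay below the median of the array at 3.28 and 3.16, a difference of -0.12, and the mean of both probe sets differed by -1.22. The target gene was therefore lower in the array labelled knock-down in both lines.

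The study is known to concern p53-dependent apoptosis and Zac1 (PLAGL1), a zinc finger protein encoded by an imprinted gene that can induce apoptosis and growth arrest. Plagl1 was among the genes with the highest differences in LM8, where its bright probe set read 8.53 in the control array and 9.91 in the knock-down array, a difference of 1.38 or 2.60-fold higher. That probe set is marked as shared between transcripts. The other mouse probe sets, whose names end in neither _x_at nor _s_at, lay below the array median and differed by 0.41 and -0.03. Without marked probe sets the gene was therefore not kept in LM8. In A375M all 3 PLAGL1 probe sets lay below the array median and are marked as shared between transcripts. The probe set with the highest mean read 2.82 in the control array and 4.00 in the knock-down array, a difference of 1.18 at a level where the array gives little signal over background. The others differed by 0.33 and 0. The PLAGL1 imprinted network list, Plagl1 included, had a median of 0.035 over 11 genes in LM8, and without a kept PLAGL1 probe set -0.033 over 9 genes in A375M, neither apart from random lists.

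**Figure D1:**
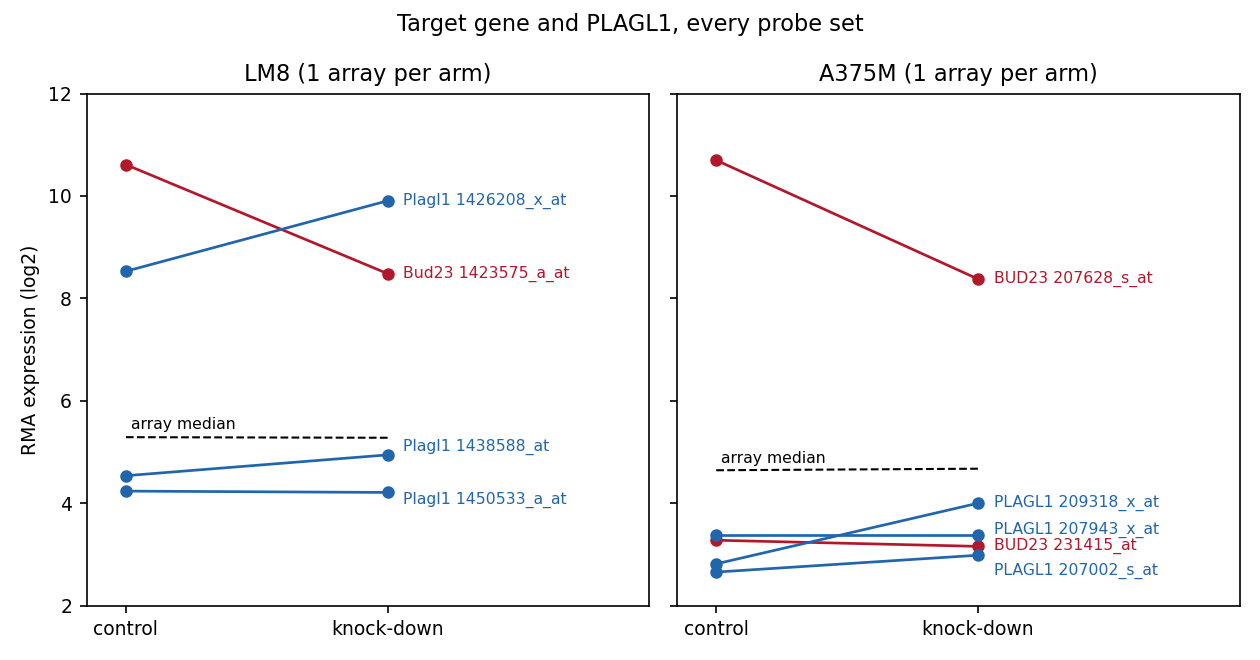
RMA expression (log2, vertical axis) of every probe set of the target gene (red) and PLAGL1 (blue) in the control and knock-down array of LM8 (left) and A375M (right), with each point 1 array and the dashed line the median of non-control probe sets. The bright target probe sets differ by -2.13 in LM8 and -2.32 in A375M, and the bright mouse Plagl1 probe set lies 1.38 higher while all human PLAGL1 probe sets lie below the array median.

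Transcripts of p53 targets went in both directions in LM8, with the list slightly below random lists, and had a median of 0 in A375M. Cdkn1a, which encodes the cell cycle inhibitor p21, differed by -0.26 and -0.29 on its probe sets in LM8, and CDKN1A by 0.077 in A375M. Mdm2, which encodes the ubiquitin ligase that degrades p53, differed by -0.22 and -0.29 on its kept mouse probe sets and by 0.04 on a dim one. The 10 human MDM2 probe sets ranged from -0.17 to 0.42, and the brightest read 10.58 in both arrays. BAX, which encodes a pro-apoptotic pore protein, differed by -0.15 and -0.17 in A375M. Over the p53 target list the median difference in LM8 was -0.066 (23 genes, 13 lower, 9 higher, percentile 2.12 among random lists), with Sesn2 at -0.59, Sesn1 at 0.54, Plk2 at 0.53 and Btg2 at -0.45. The list was not below the limit without the filter on low values (-0.023) or with the stricter filter (-0.045). In A375M the list held 27 genes. The apoptosis regulators had a median of 0.037 in LM8 (20 genes) and -0.032 in A375M (21 genes), neither apart from random lists.

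In LM8, 18 of 11646 kept genes were at least 2-fold higher in the knock-down array and 37 were at least 2-fold lower. The genes with the highest differences included extracellular matrix components and a matrix protease. Col3a1, a fibrillar collagen, differed by 2.37, Mmp13, a collagenase, by 2.08, Mgp, an inhibitor of calcification, by 1.15 and Postn, the matrix protein periostin, by 1.15. Pde7b and Pde4b, which encode enzymes that degrade cyclic AMP, differed by 1.94 and 1.46, the latter by 0.99 to 1.46 over its kept probe sets. Also among the 12 highest were the monooxygenase gene Fmo1 (2.31), the organic anion transporter gene Slco1a5 (1.80), Plagl1 (1.38), the paired-box transcription factor gene Pax8 (1.22), Txnip (1.19, and 0.72 on its other kept probe set), whose product binds thioredoxin, and Crybg1 (1.18). The lowest difference was that of Klk4, a secreted serine protease gene, which read 7.77 in the control array and 5.12 in the knock-down array, 6.27-fold lower. Next came Gask1b (-2.35), Cnmd (-2.34), which encodes a cartilage glycoprotein, and Bud23 itself. The other genes of the 12 lowest were Rgs8 (-1.65), a regulator of G-protein signalling, Ccng2 (-1.60), which encodes cyclin G2, Fgl1 (-1.57), Fetub (-1.55), Eno2 (-1.53), a glycolytic enolase, Ndrg2 (-1.51), Rgcc (-1.49) and Ramp1 (-1.43). In 3 of the 18 higher genes, Pde7b, Fmo1 and Crybg1, the control value lay below the array median, and in 7 of the 37 lower genes, Klk4, Gask1b and Cnmd among them, the knock-down value did, so the size and rank of these differences are imprecise. Of the 17 genes at least 2-fold different in LM8 that had several kept probe sets, 16 differed in the same direction on all of them. The count of higher genes was 10 with the mean of a gene's probe sets and 10 with 32 added to the linear values. The count of lower genes was 20 with 32 added and 22 with the filter at the 70th percentile.

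Interferon-stimulated genes were lower in the LM8 knock-down array. Of 26 kept members, 21 were lower and 5 higher, 8 were at least 1.5-fold lower and 4 at least 2-fold lower, and the median difference was -0.39, below all 10000 random lists of the same size and expression level. Mx2, an antiviral GTPase gene, differed by -1.41, Rsad2, which encodes viperin, by -1.32, Oas2, an oligoadenylate synthetase gene, by -1.22 and Irf7, a transcription factor gene of the interferon response, by -1.06. Rsad2 had 3 kept probe sets, all lower, while Mx2, Oas2 and Irf7 had 1 each. On the same arrays leukocyte markers had a median of -0.11 (7 genes, percentile 10.1), and spike-in transcripts added before labelling were 0.14 higher in the knock-down array.

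Stress and nutrient response genes were also lower in LM8. In the unfolded protein and ATF4 list 27 of 30 genes were lower, with a median of -0.19, below all random lists. Its members with the largest differences were Nupr1 (-0.90), a stress-induced chromatin protein gene, Cth (-0.83), of cysteine synthesis, Chac1 (-0.73), which encodes a glutathione-degrading enzyme, and Sesn2 (-0.59), which is also in the p53 list and had kept probe sets of both signs. In the hypoxia and glycolysis list 24 of 27 genes were lower, with a median of -0.18, again below all random lists, led by Eno2 (-1.53), Ankrd37 (-1.28), Adm (-0.97), the adrenomedullin gene, and Ndrg1 (-0.59). Among immediate early genes 22 of 32 were lower, with a median of -0.11 (percentile 0.04). Egr1 differed by -1.23, Fos by -0.93 and Ier3 by -0.92, while Dusp5 differed by 0.55. The immediate early list lost its place outside the limits without the filter (-0.055) and with the stricter filter (-0.034).

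The extracellular matrix list and the epithelial-mesenchymal transition list, which holds markers of both states, had medians above those of random lists in LM8. Of 35 extracellular matrix and protease genes 26 were higher, with a median of 0.11 (percentile 99.96), led by Col3a1, Mmp13, Postn and Col4a1 (0.63). Of 13 genes of the epithelial-mesenchymal transition list 10 were higher, with a median of 0.20, above all random lists. Its largest differences were those of the transcription factor genes Zeb1 (0.73), Snai1 (0.44), Tcf4 (0.35) and Prrx1 (0.31), the last with kept probe sets of both signs. Snai1 read 5.36 in the control array, close to the array median of 5.29. The epithelial genes of that list, Epcam (0.28) and Tjp1 (0.17), were higher as well, although Epcam was at -0.23 with the mean of its probe sets. Zeb2 differed by -0.28, and the mesenchymal genes Vim (0.026), Snai2 (-0.013), Twist1 (0.030) and Twist2 (-0.035) differed little. Fibroblast and smooth muscle markers, which share Col3a1 with the matrix list, had a median of 0.11 (9 genes, percentile 94.98). With the mean of a gene's probe sets both the matrix and the transition list lay within the limits (0.058 and 0.010), and the transition list did so without the filter (0.028).

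In A375M, 11 of 13244 kept genes were at least 2-fold higher in the knock-down array and 6 were at least 2-fold lower. CDCA7L read 4.67 in the control array and 7.09 in the knock-down array, a difference of 2.42. Its control value lay just above the array median of 4.64, so the size of this difference is imprecise. LIN28B, which encodes an inhibitor of let-7 microRNA maturation, differed by 2.16, the testis-expressed gene TEX15 by 1.65 and DCLK1, a microtubule-associated kinase gene, by 1.45. GALNT14, a glycosyltransferase gene, differed by 1.41, the cancer-testis antigen gene GAGE1 by 1.37, SILC1 by 1.35 and LDB2 by 1.29. PLN, which encodes phospholamban, differed by 1.09 to 2.33 over 3 kept probe sets, and CD36, a fatty acid receptor gene, by 1.05 to 1.47 over 3. FRG2EP (1.02) and the angiotensinogen gene AGT (1.00) completed the 12 highest. In 6 of the 11 genes at least 2-fold higher, LIN28B, DCLK1, GAGE1, SILC1, LDB2 and FRG2EP, the control value lay below the array median, so the size and rank of their differences are imprecise. The same holds for the knock-down value of JSRP1 among the lower genes named next. After BUD23, the lowest differences among genes whose kept probe sets had the same sign were those of CCL2 (-1.20), a monocyte chemokine gene, JSRP1 (-1.04), TPRG1L (-1.03), SHCBP1 (-1.03), COL12A1 (-0.98), FBLN5 (-0.88), IL1A (-0.88), a cytokine gene, DSP (-0.87), which encodes desmoplakin, TULP4 (-0.77), TGFBI (-0.73) and ZZZ3 (-0.71). The other kept probe set of some of these genes differed by less, namely -0.043 for ZZZ3, which is within the spread between probe sets, -0.48 for COL12A1, -0.58 for TULP4 and, among the higher genes, 0.54 for SILC1. TPP1, which encodes a lysosomal peptidase, was the remaining gene at least 2-fold lower. It was left out of the 12 because its kept probe sets differed in sign, and it is named after its values were seen. Its bright probe sets differed by -1.94 and -1.83 and its dimmer ones by -0.17 and 0.25, the last being the only probe set not marked as shared between transcripts. The count of higher genes was 5 with the filter at the 70th percentile, 7 with the mean of a gene's probe sets and 2 with 32 added to the linear values. The count of lower genes was 3 without probe sets marked as shared between transcripts and 2 with 32 added. Repeated quantile normalization gave 13 higher and 4 lower.

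Of all human probe sets 45.4% had exactly the same value in both arrays, against 0.705% of mouse probe sets. As a result the median of many A375M lists was exactly 0, and small shifts could place a list outside the limits. Inflammatory and NF-kB target genes were lower in the A375M knock-down array, with 20 of 28 lower, 4 higher and 4 identical, a median of -0.10 below all random lists, and CCL2, IL1A, CXCL2 (-0.70) and PTGS2 (-0.60), the inducible cyclooxygenase gene, at least 1.5-fold lower. Of 29 adhesion receptor genes 19 were lower (median -0.086, percentile 0.01), with the integrin genes ITGA5 at -0.43, ITGA11 at -0.40, ITGB3 at -0.32 and ITGB8 at -0.30. The 6 kept ITGB3 probe sets were of both signs, and the gene was at 0.097 without probe sets marked as shared between transcripts. Of 18 cholesterol synthesis genes 12 were lower (median -0.14, percentile 0.04), with INSIG1 at -0.43, STARD4 at -0.33, MSMO1 at -0.28 and HSD17B7 at -0.27. Of 30 G2/M cell cycle genes 25 were lower and 0 higher (median -0.079, percentile 0.37), with the proliferation marker gene MKI67 at -0.57, CENPF at -0.28, TPX2 at -0.22 and CENPE at -0.21. Of 27 TGF-beta and BMP target genes 15 were lower (median -0.051, percentile 1.44), with TGFBI at -0.73, FST at -0.56, ID4 at -0.50 and TGFBR1 at -0.44. That list was within the limits without the filter (-0.011), after repeated quantile normalization (0) and with 32 added (-0.033).

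Among lists higher in A375M, 8 of 11 genes of the core histone list, which also holds linker histones, were higher (median 0.11, percentile 99.98). H2AC6 was at 0.24, H2BC5 at 0.19, H2BC12 at 0.19 and the linker histone gene H1-2 at 0.17. Without probe sets marked as shared between transcripts the median was 0.027 and within the limits. Of 41 oxidative phosphorylation genes 29 were higher (median 0.028, percentile 99.98), and the median was -0.0016 after each array was centred on its own median, which moves all genes alike and left the list at percentile 99.98. COX7A2 differed by 0.21, COX5B by 0.14, NDUFS7 by 0.13 and NDUFS1 by -0.15, with kept COX5B probe sets of both signs. Of 10 osteoblast markers kept in A375M 7 were higher (median 0.092, percentile 99.63), with PTH1R at 0.53, DLX5 at 0.19, BMP4 at 0.14 and COL1A1 at 0.13, the last with another kept probe set identical in both arrays. The control value of PTH1R (4.34) lay below the array median (4.64), and those of DLX5 (5.55) and BMP4 (5.42) were low as well. The osteoblast list was at 0 without the filter and at -0.0052 without the shared probe sets. Melanocyte markers, of which 85% exceeded the array median in both A375M arrays, had a median of 0. Neural markers did so to 84.6% and the remaining marker lists to 50% to 62.5%, so this share does not single out melanocytes.

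**Figure D2:**
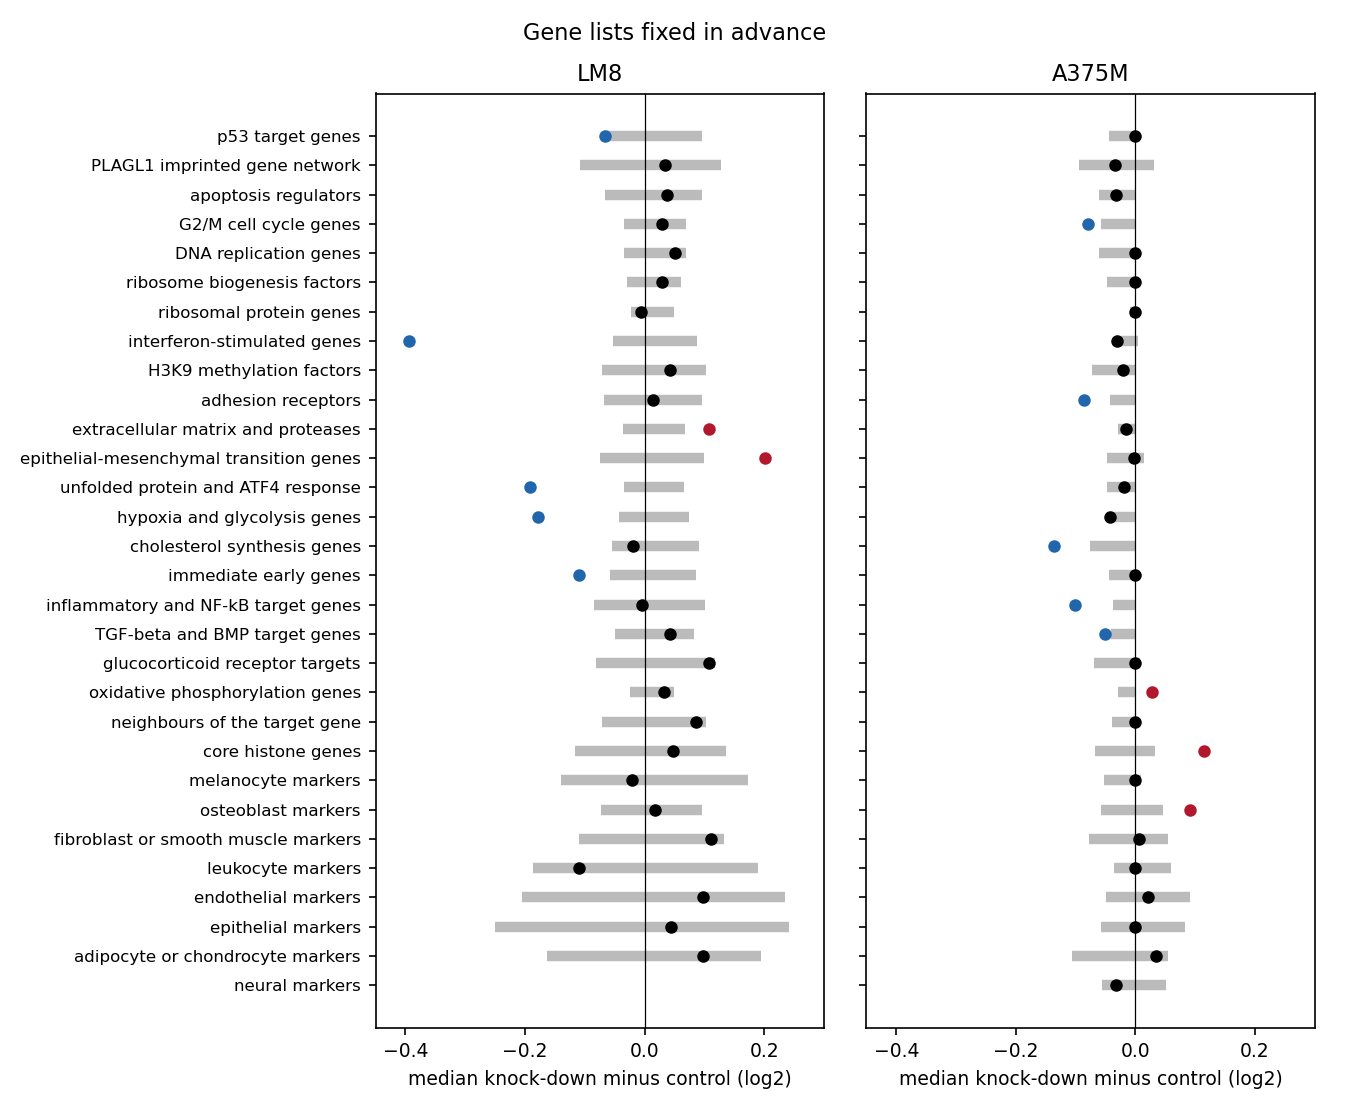
Median difference (log2, knock-down minus control, horizontal axis) of each list in LM8 (left) and A375M (right), with the grey bar the central 95% of the medians of 10000 random lists and blue or red points the medians below or above it. Interferon-stimulated genes in LM8 lie farthest out at -0.39, and the red oxidative phosphorylation point in A375M (0.028) was at -0.0016 when the arrays were centred, still at percentile 99.98 among random lists.

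Over all 59 comparisons of a list with random lists, 15 lay outside the limits, 7 of 29 in LM8 and 8 of 30 in A375M, where 2.95 are outside by the construction of the limits. The target gene acts in ribosome synthesis, and neither ribosome biogenesis factors (0.028 over 34 genes in LM8, 0 over 31 in A375M) nor ribosomal protein genes (-0.0054 over 43 genes, 0 over 52) stood apart. The neighbours of the target gene in the Williams-Beuren region had medians of 0.087 over 18 genes in LM8 and 0 over 21 in A375M. The other lists within the limits in LM8 had medians of 0.029 for G2/M genes, 0.051 for DNA replication, 0.043 for H3K9 methylation factors, 0.014 for adhesion receptors, -0.020 for cholesterol synthesis, -0.0045 for inflammatory genes, 0.043 for TGF-beta and BMP targets, 0.11 for glucocorticoid receptor targets, 0.032 for oxidative phosphorylation and 0.048 for the core histone list. Markers of melanocytes (-0.020), osteoblasts (0.017), endothelium (0.098), epithelium (0.044) and adipocytes or chondrocytes (0.099) were within them too, and neural markers had 4 kept genes, too few for a median. In A375M the corresponding medians were 0 for DNA replication, -0.021 for H3K9 methylation factors, -0.016 for extracellular matrix, -0.0031 for the transition list, -0.019 for the unfolded protein and ATF4 list, -0.043 for hypoxia and glycolysis (percentile 2.98), -0.032 for interferon-stimulated genes (percentile 2.80), 0 for immediate early genes and 0 for glucocorticoid receptor targets. The interferon-stimulated genes lay below the limit in A375M without probe sets marked as shared between transcripts (-0.15, percentile 0.02), without the filter (-0.020, percentile 0.925) and with 32 added (-0.028, percentile 2.37). Marker medians there were 0.0053 for fibroblast or smooth muscle, 0 for leukocytes, 0.021 for endothelium, 0 for epithelium, 0.034 for adipocytes or chondrocytes and -0.032 for neural cells. The median and the mean had opposite signs for 6 lists in LM8 and 2 in A375M, none of them outside the limits.

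The design also asks whether the knock-down gave the same differences in both lines. Of 8981 genes kept in both, matched by symbol, BUD23 was the only gene at least 2-fold lower in both lines and 0 genes were at least 2-fold higher in both, where independent lists of the same lengths would share 0.011 and 0.0024. With arrays centred on their medians MEGF10 (-1.01 in LM8, -1.02 in A375M) joined BUD23, and without probe sets marked as shared between transcripts, which leaves out the bright human BUD23 probe set, 0 genes were lower in both. Without the filter on low values 1 gene was at least 2-fold higher in both, PLAGL1 (1.38 in LM8 and 1.18 in A375M), among 13637 genes, and 1.74% of 10000 random re-pairings of genes gave at least 1. That human PLAGL1 probe set lay below the array median in both arrays, and the one brighter in the control array (3.38) differed by 0, so a shared difference is not established. The PLAGL1 probe sets behind both values are also marked as shared between transcripts. At the 1.5-fold threshold MEGF10 (-1.02 in LM8, -0.99 in A375M as deposited) joined BUD23, and the phosphodiesterase gene PDE7B was higher in both (1.94 and 0.71). Independent lists would share 0.30 lower and 0.10 higher genes at this threshold, and the 2 lower genes and 1 higher gene seen lay within the central ranges of random re-pairings of genes, 0 to 2 and 0 to 1. The kept human MEGF10 probe sets were of both signs. Across the 8981 genes, which are not independent replicates, the differences in LM8 and A375M had Pearson's r of 0.033 and Spearman's rho of 0.0080, and r was 0.014 without the target gene.

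**Figure D3:**
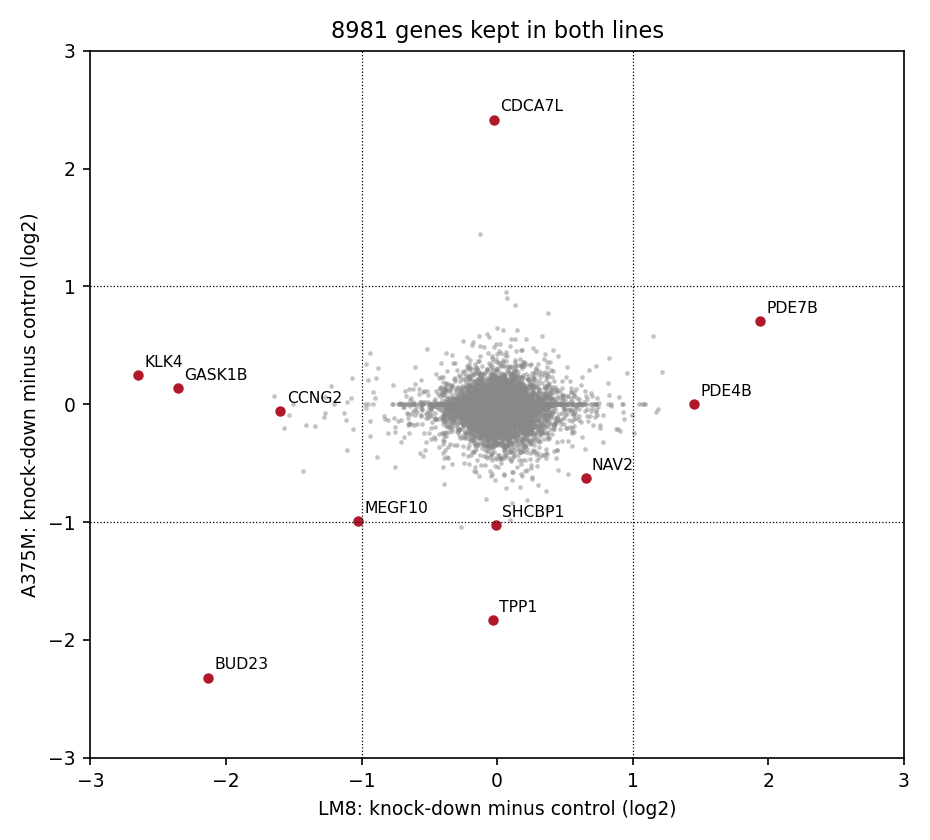
Each point is 1 of 8981 genes kept in both lines, with its difference (log2, knock-down minus control) in LM8 on the horizontal and in A375M on the vertical axis, dotted lines at 2-fold and named genes in red. BUD23 is the only point beyond 2-fold in the same direction on both axes, and the points form no diagonal (Pearson's r 0.033 across genes).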

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

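The tests of a shift or trend and of single probe sets for the interferon-stimulated genes, of their median in A375M, of the depth of the knock-down, and of the TPP1 probe sets were chosen or worded after the values were seen. The difference of NAV2, which encodes a microtubule-associated protein, was 0.65 in LM8 and -0.63 in A375M, so the lines lay in opposite directions at the 1.5-fold threshold. With 1 array per group the difference between the lines was not tested, and the other kept human NAV2 probe sets were identical in both arrays. Among probe sets above the array median that name no gene or several, some were at least 2-fold different. Without a symbol there were 6 of 1972 in LM8 (2 higher, 4 lower) and 3 of 2685 in A375M (3 higher). With several symbols there were 5 of 581 in LM8 (1 higher, 4 lower) and 4 of 1165 in A375M (4 higher), the last being the GAGE probe sets described among the other observations.

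Interferon-stimulated genes were lower in the LM8 knock-down array by a median of -0.39. A global shift or an intensity-dependent trend is argued against as the whole cause, since genes of the same level did not fall alike. The median lay below the lowest of 10000 random lists matched on level (-0.15) by -0.24. The spread between probe sets is 0.12, though for single genes and not for a list median. This comparison restates the place among random lists already reported and is no separate support. Removal of a loess curve on mean level left all 15 lists outside the limits, this one included. Single probe sets are argued against for the 8 members with several kept probe sets. Those that the list did not use had a median of -0.29, with 11 of 12 lower. The other members, Mx2, Oas2 and Irf7 among them, had 1 kept probe set each, so this comparison does not cover them. A response common to both lines stays open, since 17 genes kept in both had a median of -0.037 in A375M (95% bootstrap interval over genes -0.18 to -0.0057) against -0.20 in LM8 (-0.13 to -0.0027 in A375M over 8 other settings, lowest without probe sets marked as shared between transcripts and highest with quantile normalization repeated), and the interval reaches past the bound of -0.099 set from the LM8 value. An unrelated difference between the derived LM8 lines cannot be told apart from an effect of the knock-down, because each group holds 1 array.

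A375M had 17 genes at least 2-fold different (0.128% of kept genes) and LM8 had 55 (0.472%). Among 9169 A375M genes whose values were not identical the share was 0.185% (95% Wilson interval 0.116% to 0.297%, counting error only), below the interval of LM8 (0.363% to 0.614%). The identical values of the human table stay open all the same, since that share follows from the number of genes left out and does not test whether the step behind the recurring values also shrank other differences. A weaker knock-down stays open, since the target difference in A375M minus that in LM8 was -0.19 on the bright probe sets but 0.91 with the mean of a gene's probe sets, which takes in a dim human one, and the array designs differ. Differences between the lines, the array designs and the processing of each table also stay open and were not tested.

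TPP1 was lower in the A375M knock-down array. An artefact of 1 probe set is argued against, since the second lowest difference among its probe sets was -1.83, although the dimmer probe sets differed by -0.17 and 0.25. The last is the only one not marked as shared between transcripts, so without marked probe sets the gene was not lower. A response common to both lines is argued against, since Tpp1 differed by -0.029 in LM8, and by 0.31 on its other probe set. An off-target effect of the human hairpin stays open, since its sequence was not used here and only 2 genes, BUD23 and TPP1, were at least 3-fold lower in A375M.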

How the results depend on the processing

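The fit with cell line as the replicate block, and the mean of probe sets for the target gene, were chosen after the values were seen. The former took the 2 lines as a pair of replicates of the knock-down, in limma on 8981 genes with 1 residual degree of freedom, and called 0 genes higher and 1 lower (BUD23, adjusted p 0.017) at an adjusted p under 0.05, with 108 higher and 170 lower at an unadjusted p under 0.05. The unadjusted counts together are below 0.05 of the 8981 genes, so there was no excess of small p-values. Many A375M differences were exactly 0, which can hold these counts down. The counts therefore do not decide whether smaller differences were shared by the lines. Within a line each group holds 1 array, so there was no paired fit and no replicate could be left out. Signal over background limits genes below the array median. The filter needs a gene above it in 1 array only, so in LM8 3 of 18 higher and 7 of 37 lower genes, and in A375M 6 of 11 and 1 of 6, lay at or below it in the other array. The cause was not tested where the alternative's own construction (fewer genes kept, another threshold, shrunken differences) does not show it. The target difference of -2.13 in LM8 moved by less than the spread between probe sets in every alternative run, and that of -2.32 in A375M was -2.21 with 32 added to the linear values, -1.22 with the mean of its probe sets and -0.12 on its dim second one, which enters that mean. Genes at least 2-fold higher in LM8 (18) numbered 10 with the mean of a gene's probe sets, 10 with 32 added, 135 at 1.5-fold and 5 at 3-fold. Those lower (37) numbered 22 with the filter at the 70th percentile, 20 with 32 added, 153 at 1.5-fold and 6 at 3-fold. Genes higher in A375M (11) numbered 5 with the filter at the 70th percentile, 7 with the mean of probe sets, 2 with 32 added, 50 at 1.5-fold and 3 at 3-fold. Those lower (6) numbered 3 without _x_at and _s_at probe sets, 2 with 32 added, 49 at 1.5-fold and 2 at 3-fold. Genes higher in both lines (0) numbered 1 without the filter (PLAGL1, on a human probe set below the array median) and 1 at 1.5-fold (PDE7B). Those lower in both (1) numbered 2 with arrays centred on their medians (BUD23 and MEGF10), 0 without _x_at and _s_at probe sets, which leaves out the bright human BUD23 probe set, and 2 at 1.5-fold.

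Of the 15 list medians outside the limits, those of 8 lists stayed outside them on the same side under every alternative run. The median of p53 targets in LM8 was within the limits without the filter (-0.023) and with the filter at the 70th percentile (-0.045), and so were immediate early genes in LM8 (-0.055 and -0.034). In LM8 the matrix list was within them with the mean of probe sets (0.058), and the transition list with the mean of probe sets (0.010) and without the filter (0.028). In A375M the TGF-beta and BMP list was within them without the filter (-0.011), with quantile normalization repeated (0) and with 32 added (-0.033), and histones without _x_at and _s_at probe sets (0.027). Oxidative phosphorylation genes in A375M, 1 of the 8, had a median of -0.0016 with the arrays centred, a shift common to all genes that says nothing about the list and left it at percentile 99.98. Osteoblast markers in A375M were at 0 without the filter and reversed to -0.0052 without _x_at and _s_at probe sets. Of 382 comparisons for the lists within the limits 367 stayed there and 15 moved outside, among them interferon-stimulated genes in A375M without _x_at and _s_at probe sets (-0.15, percentile 0.02). Some named genes changed sign. With the mean of probe sets Tpp1 (0.14), Epcam (-0.23), Fn1 (-0.039) and Vim (-0.0057) did so in LM8, and without _x_at and _s_at probe sets ITGB3 (0.097) and TPP1 (0.25) in A375M. MAGEA6 was at -0.00014 with arrays centred, again by a shift common to all genes, and MAGEA12, near 0 throughout, changed sign with quantile normalization repeated (0.032) and with the loess curve removed (0.0095). With 32 added, 28 of 47 named genes that had been at least 2-fold different were still so, and with the mean of probe sets 34 of 40.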

Other observations

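Cyclic nucleotide phosphodiesterase genes, whose products degrade cyclic AMP or cyclic GMP, included several with higher values in the LM8 knock-down array. The members counted include Pde6d (-0.088 in LM8), whose product is a subunit without that activity. The family was chosen after Pde7b and Pde4b were seen among the highest differences, so its place among random lists is not independent of that choice. Of 11 kept members 5 were at least 1.5-fold higher and 0 at least 1.5-fold lower, and the median difference was 0.43 (0.42 to 0.44 over 3 other scalings of the arrays). Without Pde7b and Pde4b the median was 0.26 over 9 members, 6 of them higher and 3 lower. Besides Pde7b (1.94) and Pde4b (1.46), those at least 1.5-fold higher were Pde8a (0.84), Pde4d (0.82) and Pde5a (0.72), while Pde3a differed by -0.38. In A375M the 15 kept members had a median of 0 (-0.030 to 0.049 over the other scalings), with PDE7B at 0.71. Among regulators of G-protein signalling, also chosen after the values were seen, Rgs8 (-1.65), Rgs16 (-1.10) and Rgs11 (-0.78) were at least 1.5-fold lower in LM8, while Rgs2 and Rgs10 differed by 0.51 and 0.49 and the median over 11 members was -0.029 (-0.018 to 0.0043 over the other scalings).

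In A375M the GAGE family of cancer-testis antigens was higher in the knock-down array. The family was chosen after the values were seen. All 4 probe sets that match several GAGE members were 1.07 to 1.20 higher, from bright levels (9.52 to 9.70 in the control array), and GAGE1 was 1.37 higher at a dim level. These sequences are near-identical, so the probe sets do not tell the members apart. PAGE1 differed by 0.91, whereas the 16 kept cancer-testis genes of the GAGE, PAGE, XAGE, MAGE, SSX and CTAG families had a median of 0 and only GAGE1 and PAGE1 among them differed by at least 1.5-fold. The bright MAGEA4, MAGEA6 and MAGEA12 differed by 0.05, 0.03 and -0.0033, with MAGEA6 at -0.00014 after centring, which shifts all genes alike, and MAGEA12 at 0.032 after repeated quantile normalization and 0.0095 after removal of the loess curve.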
